A study of Homo sapiens with 6 samples.

How the data were processed

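The data were mRNA sequencing libraries of 3 wild-type and 3 CCM3-knockout CI-huVEC lines, prepared from total RNA with a stranded mRNA kit, per the labels' protocols. STAR and HTSeq are named, without versions and with the genome builds hg19 and GRCh37, per the submitters' processing notes. The gene annotation, the strand setting of the counting and any filters are not given in the sources used here, so overlapping and antisense genes are uncertain. The deposited count table gave whole-number counts per gene symbol and library, not normalized, per the file headers and values. In the same table the authors gave FPKM; the ratio of count to FPKM differed between samples by 1 factor for all genes, with a departure of at most 0.0115% over 3056 genes with more than 2000 counts, and that factor departed from the library totals by at most 0.3832%. A further deposited table held the authors' own comparison, per the file headers: a mean normalized signal per gene (baseMean), a log2 fold change with its standard error, and a p-value with an adjusted p-value. Its tool is not given in the sources used here. Its direction, knockout over wild type, was checked against the counts.

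The count table had 28514 rows, 20830 of them with a count. Of these rows, 13 carried a date in place of a gene name, 11 with counts, and they took between 0.175% and 0.196% of each library's counts; they were kept in the totals. No mitochondrially encoded symbol was found, so that list was not tested. A current symbol was found for 22813 symbols, from a gene name table. Chromosomes and neighbouring genes came from the RefSeq gene table of the assembly GRCh38.p14 and no coordinates were used, since the files use another build. Total counts ranged from 28280417 to 32919491 per library. At this depth 3 counts corresponded to 0.091 to 0.106 CPM.

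Replicates were compared before averaging. The chi-square per degree of freedom over genes was 2.16 to 4.47 for pairs of wild-type libraries and 21.0 to 74.4 for pairs of knockout clones, so no library was counted as a duplicate. Wild-type replicates 1, 2 and 3 are WT 1, WT 2 and WT 4, and knockout replicates 1, 2 and 3 are K17, K18 and K19. These numbers were given in listing order and pair nothing.

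The test was the edgeR quasi-likelihood F test (glmQLFit with robust estimation, two-sided) on the counts, with TMM factors and the default filterByExpr filter (a minimum count of 10, and 15 in total), which left 14548 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called below 0.05. Levels are CPM with TMM factors, as mean ± SD of 3 libraries. Log2 fold changes are knockout over wild type. Gene lists fixed before the data were examined numbered 33, and the 31 with at least 5 tested genes were tested by limma's camera on log2 CPM (prior count 3) with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and limma's fry were alternatives. All 6 camera calls were lost with an estimated correlation, and fry, which tests whether members move on balance in 1 direction without comparing them to other genes, called 19 lists, 5 of the 6 among them. The estimated correlation was -0.004 for the KLF2/KLF4 list and -0.017 for the pan-endothelial and NRF2 lists. These values lie below the preset 0.01, so correlation among members does not account for the loss of those calls. Ratios with few counts are given with exact 95% counting intervals, and a group with 0 counts was set at a floor of 3 counts over the group.

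The genes named were set by a rule fixed before the data were examined. It took PDCD10, its partners and 12 other genes by name, the 12 largest increases and 12 largest decreases among called genes with at least 5 CPM in a group and no overlap of the groups, and up to 4 called members per list, 2 in each direction, with the smallest adjusted p. Genes named outside it are said to be so. A fixed list and some genes the rule takes are not reported here.

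Alternatives were other scalings (DESeq2 size factors, upper quartile, library totals, the 20 most abundant genes left out), no filter or a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, edgeR without robust estimation, limma on log2 of FPKM plus 1 or 0.1, stricter thresholds, and each library left out. Chosen after seeing the data were limma-voom with quality weights per group, thinning of all libraries to 28280417 counts, and removal of a lowess trend of each library on GC content (span 0.3). GC content was the median over the transcripts of a gene in GENCODE, matched by symbol for 13248 genes (91.1% of those tested and 93.7% of those called).

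The edgeR fit was tested on counts simulated from these libraries for 14409 genes. It recovered 34.3%, 85.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and called 0.08% of unchanged genes. The simulation gave both groups the same spread per gene and held no GC-content trend. In the data the biological coefficient of variation was 3.87% in the wild type and 24.5% in the knockouts. These shares may therefore not hold for the real comparison. Camera called 20 of 20 simulated lists changed 1.5-fold and 1 of 180 unchanged lists, over 14419 genes. Genes were simulated independently of each other. This therefore does not show how camera performs on lists with correlated members, such as the cell cycle list (estimated correlation 0.493). The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.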

Results

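Messenger RNA was sequenced from 6 libraries of CI-huVEC, an immortalised line of human umbilical vein endothelial cells. The first group held 3 wild-type lines (WT 1, WT 2 and WT 4). The other group held 3 clonal lines (K17, K18 and K19) in which exon 3 of CCM3 had been targeted by CRISPR/Cas9 editing. CCM3 is the disease name of the gene PDCD10, which is mutated in familial cerebral cavernous malformations. All 6 samples were taken at passage 31. The comparison asks how transcript levels differ between the wild-type lines and the CCM3-knockout clones. For every gene, an effect of CCM3 loss cannot be told apart from a difference between clones and the wild-type lines. Total counts were 32919491, 32512367 and 28392460 in WT 1, WT 2 and WT 4, and 29101994, 28280417 and 29834621 in K17, K18 and K19. All 6 samples carry the same clone label (HKO), whose meaning is not given, and the labels do not say whether the wild-type lines came from separate clones, so p-values measure only the spread between these samples, which may be partly technical. Counting intervals and floors cover counting error only.

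In the knockout clones the transcription factors KLF2 and KLF4 and their target THBD, the endothelial anticoagulant receptor thrombomodulin, rose. KLF2 went from 29.9 ± 2.20 to 114.8 ± 18.2 counts-per-million (CPM; mean ± SD, n = 3 per group), KLF4 from 10.9 ± 1.26 to 78.5 ± 5.92 and THBD from 11.6 ± 0.136 to 137.1 ± 28.03. Transcripts of the matrix glycoprotein fibronectin (FN1) fell from 9936 ± 392 to 1886 ± 252 CPM, and those of periostin (POSTN), another matrix protein, from 137.2 ± 8.17 to 0.198 ± 0.163 CPM. The kinase gene MST4 (current symbol STK26), whose product binds the CCM3 protein, fell from 17.1 ± 0.46 CPM to 0.151 ± 0.079 CPM. Endothelial receptor genes such as KDR and TEK rose, while most called genes of the TGF-beta and BMP pathway fell. Since 38.7% of all tested genes were called, called members alone do not set a gene list apart.

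**Figure D1:**
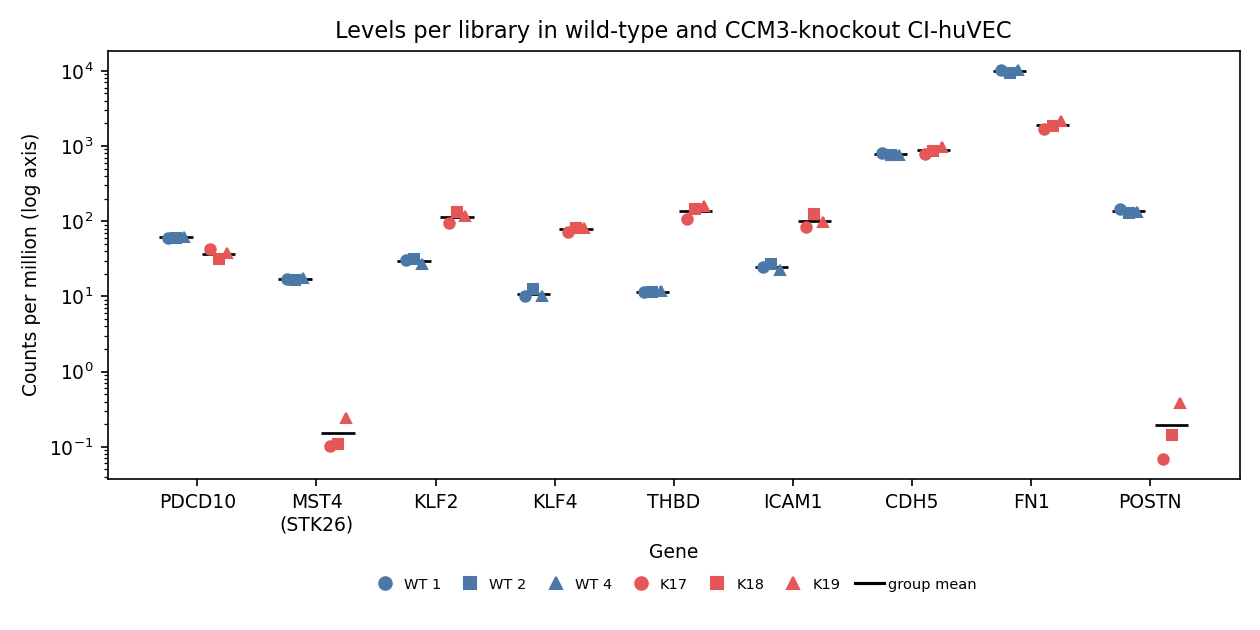
CPM (log axis) of 9 genes in each library; blue symbols are wild-type libraries, red symbols are knockout clones, and black bars are group means of 3. PDCD10, MST4, FN1 and POSTN lay lower in every knockout clone than in every wild-type library, and KLF2, KLF4, THBD and ICAM1 lay higher, while the CDH5 values of the groups overlapped.

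The targeted gene itself was still transcribed. PDCD10 measured 60.5, 60.7 and 61.6 CPM in WT 1, WT 2 and WT 4, and 42.3, 31.6 and 37.6 CPM in K17, K18 and K19, so that it fell by 0.71 on the log2 scale (SE 0.11, adjusted p = 0.00374 by the edgeR quasi-likelihood test). It was lower in 3 of 3 clones, and gene counts alone do not show the edit or the protein. Of 19 tested genes for the CCM complex and the STRIPAK phosphatase complex, 8 were higher, 2 lower and 9 not called (8 and 2 adjusted over the list alone), and the list was not called by camera (adjusted p = 0.0826). HEG1, the transmembrane receptor that anchors the CCM complex, rose by 1.55 ± 0.05 on the log2 scale (± SE) with adjusted p = 2.3e-05. CCM2L, a CCM2 paralogue, rose from 2.38 ± 0.30 to 31.4 ± 2.37 CPM with the same adjusted p. For MST4 the 1621 wild-type counts against 13 knockout counts gave a 116-fold ratio, with a 95% counting interval of 67.6 to 218. The adjusted p for MST4 was 3.04e-05. MST4 is X-linked and belongs to the genes near zero in all 3 clones, among which X-linked genes were over-represented (see Other observations). CCM2 was higher by 0.79 (adjusted p = 0.0182) and the kinase gene STK25 by 0.81 (adjusted p = 0.0293), whereas KRIT1 (0.22, adjusted p = 0.0893) and STK24 (0.11, adjusted p = 0.115) did not pass the test. Of the PDCD10 neighbours list, PDCD10 and GOLIM4 were the 2 genes deep enough to test, too few for a list test; GOLIM4 fell by 0.42 (adjusted p = 0.00548), and both stayed called adjusted over the list alone. The adjacent gene SERPINI1 was near the floor, with at most 9 counts in any library. The CCM2 call ended without WT 1, WT 2 or WT 4 (adjusted p = 0.0543, 0.0606 and 0.0763), and that of STK25 without WT 1, WT 2, WT 4, K18 or K19 (adjusted p = 0.0864, 0.0839, 0.107, 0.0732 and 0.0747) and by limma on log2 of FPKM plus 1 with no filter (adjusted p = 0.068). With the GC-content trend of each library removed, a setting chosen after seeing the data, STK25 was at 0.40 (adjusted p = 0.00515), KRIT1 and STK24 were called at 0.40 and 0.15 (adjusted p = 0.0013 and 0.0258), and the list was called higher (adjusted p = 0.0279), as it was without K18 (adjusted p = 0.0492).

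Targets of KLF2, KLF4 and the MEKK3-ERK5 kinase cascade were higher as a group. Of 18 tested members, 14 were higher, 1 lower and 3 not called (14 and 1 adjusted over the list alone). The camera call was at adjusted p = 3.25e-05, and was lost at adjusted p = 0.191 with an estimated correlation. That correlation was -0.004, below the preset 0.01, so correlation among members does not account for the loss. KLF4 rose by 2.85 (SE 0.11, adjusted p = 3.3e-05), THBD by 3.57 (SE 0.17, adjusted p = 6.39e-05) and KLF2 by 1.94 (SE 0.13, adjusted p = 0.000209) on the log2 scale. The KLF2 value was 1.29 (adjusted p = 0.00334) with the GC-content trend of each library removed. The lower member was CYP1A1, a cytochrome P450 of the aryl hydrocarbon response, which fell from 0.505 ± 0.046 to 0.140 ± 0.034 CPM (adjusted p = 0.00446). In the list of coagulation and fibrinolysis genes, 11 of 26 were higher, 5 lower and 10 not called (12 and 6 adjusted over the list alone; camera adjusted p = 0.238). The anticoagulant cofactor gene PROS1 rose from 8.47 ± 0.50 to 58.2 ± 6.81 CPM and the plasminogen activator gene PLAU from 84.8 ± 5.12 to 284 ± 27.6 CPM. The protease-activated receptor gene F2RL1 fell by 1.96 and the thromboxane synthase gene TBXAS1 by 1.97 on the log2 scale.

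Genes of endothelial identity were mostly higher. Of 28 pan-endothelial genes, 18 were higher, 4 lower and 6 not called (18 and 4 adjusted over the list alone), with a camera adjusted p = 0.00301 and adjusted p = 0.211 with an estimated correlation. KDR, the main VEGF receptor, rose from 154.8 ± 9.34 to 374.9 ± 22.6 CPM (adjusted p = 9.24e-05) and the angiopoietin receptor gene TEK from 126.1 ± 6.08 to 429.3 ± 64.9 CPM (adjusted p = 0.000216). PECAM1 rose by 0.91 (adjusted p = 0.00446) and VWF by 1.298 (adjusted p = 0.0089), with VWF at 789.6, 1243 and 611.6 CPM in K17, K18 and K19. CDH5, which codes for VE-cadherin, differed by 0.18 (SE 0.09, adjusted p = 0.137); without K17 its value was 0.25 (adjusted p = 0.00856), and with the GC-content trend removed 0.07 (adjusted p = 0.443). The fenestral diaphragm gene PLVAP and the sialomucin gene EMCN fell, by 1.39 and 2.83 on the log2 scale (adjusted p = 0.00367 and 0.0166). The EMCN call ended without WT 1, WT 2, WT 4 or K19, at adjusted p = 0.0567, 0.0503, 0.0581 and 0.0594.

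Arterial and venous markers held 1 higher, 7 lower and 5 not called among 13 tested (2 and 9 adjusted over the list alone), with a camera adjusted p = 0.0826. Fry, which does not compare members with other genes, called the list lower (adjusted p = 1.74e-05). The gap junction gene GJA5 fell from 1.18 ± 0.18 to 0.058 ± 0.021 CPM, and the Notch target gene HEY2 from 11.3 ± 0.62 to 0.335 ± 0.253 CPM. By camera the list was called lower without K18 at adjusted p = 0.0396, and with the GC-content trend removed at adjusted p = 0.0233. In the Notch list 6 of 17 genes were higher, 2 lower and 9 not called (6 and 2 adjusted over the list alone; camera adjusted p = 0.291, direction up). Its median log2 fold change was 0.26, and its mean -0.10 with NOTCH3 set at a floor of 3 counts over the knockout group. NOTCH4 rose by 1.47 (adjusted p = 0.000444) and the ligand gene DLL4 by 0.92 (adjusted p = 0.00517), while NOTCH3 went from 1.09 ± 0.11 CPM to 0 counts in all 3 clones. NOTCH1 measured 40.9 CPM in K17 and 89.1 and 99.97 CPM in K18 and K19 against 45.5 ± 4.64 in the wild type, and its difference of 0.75 was not called (adjusted p = 0.106). It was called without K17 (1.06, adjusted p = 3.51e-05), and by DESeq2 (adjusted p = 0.0296), but with the GC-content trend removed NOTCH1 was at 0.18 (adjusted p = 0.27) and DLL4 at 0.60 (adjusted p = 0.039). Lymphatic markers went both ways, with 2 higher, 3 lower and 2 not called of 7 (2 and 3 adjusted over the list alone; camera adjusted p = 0.375). LYVE1, the lymphatic hyaluronan receptor gene, rose from 25.8 ± 1.94 to 200.5 ± 92.3 CPM, while PROX1, the lymphatic master regulator gene, fell from 1.18 ± 0.22 to 0.185 ± 0.076 CPM.

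**Figure D2:**
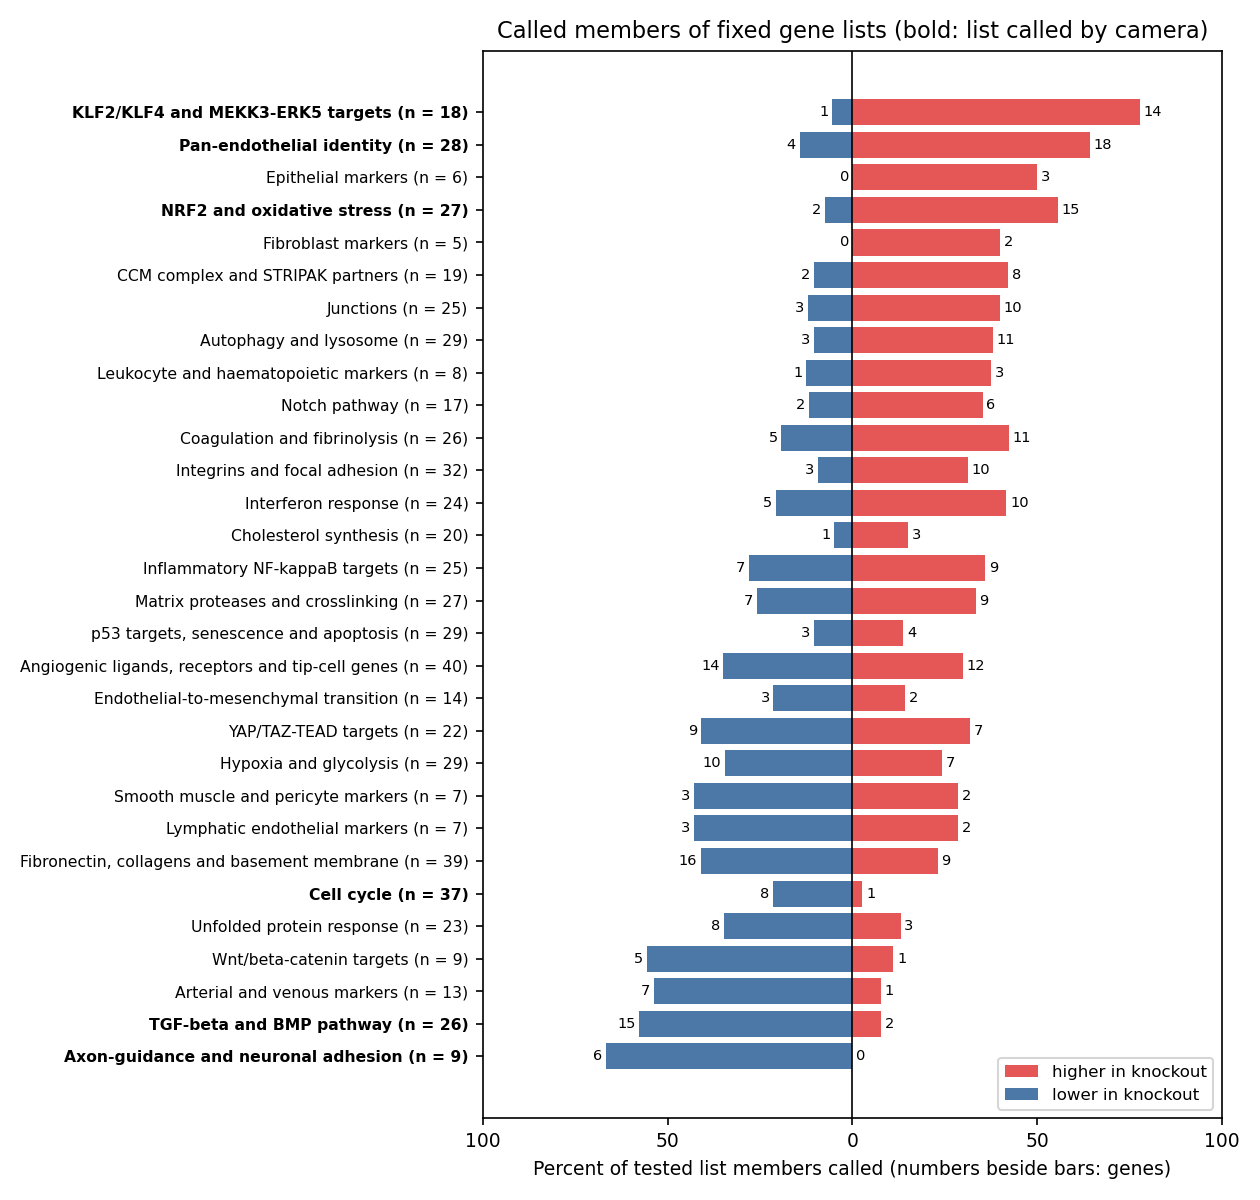
Share of tested members called higher (red, to the right) and lower (blue, to the left) in the knockouts for each list shown, all with at least 5 tested members; the number of genes stands beside each bar and list names in bold were called by camera with its preset correlation. The KLF2/KLF4 list had 14 higher and 1 lower member and the TGF-beta and BMP list 2 higher and 15 lower.

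TGF-beta and BMP pathway genes were mostly lower. Of 26 tested members, 15 were lower, 2 higher and 9 not called (15 and 2 adjusted over the list alone). Camera gave adjusted p = 0.00282, and adjusted p = 0.462 with an estimated correlation. INHBA, which codes for the activin A subunit, fell from 17.2 ± 0.45 to 1.62 ± 0.27 CPM (adjusted p = 4.75e-05), and the SMAD co-repressor gene SKIL from 157.2 ± 7.66 to 63.7 ± 7.51 CPM (adjusted p = 0.00025). The endothelial BMP9 receptor gene ACVRL1 rose by 0.82 (adjusted p = 0.0024) and the co-receptor gene TGFBR3 by 0.61 (adjusted p = 0.00518). With the GC-content trend removed ACVRL1 was at 0.42 (adjusted p = 0.0126). In the list for endothelial-to-mesenchymal transition, 2 of 14 genes were higher, 3 lower and 9 not called (2 and 3 adjusted over the list alone; camera adjusted p = 0.588). S100A4 rose from 0.492 ± 0.154 to 5.19 ± 1.18 CPM and the smooth muscle actin gene ACTA2 from 3.88 ± 0.20 to 13.5 ± 4.26 CPM, while POSTN and the actin-binding protein gene TAGLN fell. TAGLN fell by 1.05 (adjusted p = 0.0162), a call that ended without WT 1 (adjusted p = 0.0632) or WT 2 (adjusted p = 0.0525).

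Matrix genes moved in both directions. Of 39 tested genes for fibronectin, collagens and basement membrane, 9 were higher, 16 lower and 14 not called (9 and 16 adjusted over the list alone; camera adjusted p = 0.168). FN1 fell by 2.40 on the log2 scale (SE 0.10, adjusted p = 4.98e-05). The elastic fibre gene FBLN5 fell from 107.7 ± 9.51 to 0.188 ± 0.129 CPM. The fibrillin gene FBN2 rose from 130.1 ± 4.54 to 434.5 ± 44.2 CPM. Without K19 the list was called lower, at adjusted p = 0.00906. Among matrix proteases and crosslinking enzymes 9 of 27 were higher, 7 lower and 11 not called (9 and 7 adjusted over the list alone; camera adjusted p = 0.85, direction up, with a median of -0.03 and a mean of -0.42). The cathepsin gene CTSL1 (now CTSL) rose by 1.60, and the metalloproteinase genes TLL1 and ADAM12 fell by 7.19 and 2.87.

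Markers of other cell types also differed between the groups. The pericyte marker RGS5 fell from 300.6 ± 7.82 to 10.4 ± 4.98 CPM (adjusted p = 0.000331), while MCAM, shared by endothelium and pericytes, rose by 0.72 (adjusted p = 0.00126). Smooth muscle and pericyte markers held 2 higher, 3 lower and 2 not called of 7 (2 and 3 adjusted over the list alone). Camera did not call the list (adjusted p = 0.602), whereas fry called it lower (adjusted p = 0.00364). Fibroblast markers held 2 higher and 3 not called of 5 (2 and 0 adjusted over the list alone; camera adjusted p = 0.356), with PI16 at 1.17 ± 0.26 CPM in the wild type and 53.9, 120.0 and 266.1 CPM in K17, K18 and K19. The major fibroblast collagen gene COL1A1, named after its values were seen, was at 0.220 ± 0.076 CPM in the wild type and 1.26 ± 1.94 CPM in the knockouts. It was uneven among the clones, with 101 counts in the highest clone and at most 10 in any wild-type library. Epithelial markers held 3 higher and 3 not called of 6 (3 and 0 adjusted over the list alone; camera adjusted p = 0.299), KRT8 and MUC1 among those higher. Leukocyte and haematopoietic markers held 3 higher, 1 lower and 4 not called of 8 (3 and 1 adjusted over the list alone; camera adjusted p = 0.356), with CD68 higher by 0.77 and RUNX1 having fallen by 1.29.

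Adhesion genes were called in both directions, as were genes over the whole data, where 38.7% of those tested were called. Integrin and focal adhesion genes held 10 higher, 3 lower and 19 not called of 32 (11 and 3 adjusted over the list alone; camera adjusted p = 0.182). The caveolin gene CAV1 rose by 0.80 (SE 0.05, adjusted p = 9.85e-05) and the laminin-binding integrin gene ITGA6 by 1.64, while ITGAV fell by 1.44 and ITGA2 by 1.18. Junction genes held 10 higher, 3 lower and 12 not called of 25 (10 and 4 adjusted over the list alone; camera adjusted p = 0.356, direction up, with a median of 0.17 and a mean of -0.05). The tight junction genes F11R and CLDN5 rose by 0.93 and 1.41, and the gap junction gene GJA1 fell by 0.68. With the GC-content trend removed CLDN5 was at 0.79 and no longer called (adjusted p = 0.102). Among YAP/TAZ-TEAD targets 7 of 22 were higher, 9 lower and 6 not called (8 and 9 adjusted over the list alone; camera adjusted p = 0.85, direction up, median 0.07, mean -0.04). NT5E rose by 1.34 and TGFB2 fell by 1.92.

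Guidance and adhesion genes of neurons were lower as a list. Axon-guidance and neuronal adhesion genes held 6 lower and 3 not called of 9 (0 higher and 6 lower adjusted over the list alone), at camera adjusted p = 0.00955 and adjusted p = 0.411 with an estimated correlation. The neurexin gene NRXN3 fell from 7.12 ± 0.49 to 0.126 ± 0.085 CPM and the adhesion gene FLRT2 from 135 ± 8.39 to 37.1 ± 8.76 CPM. Angiogenic ligands, receptors and tip-cell genes held 12 higher, 14 lower and 14 not called of 40 (12 and 15 adjusted over the list alone; camera adjusted p = 0.588). The angiopoietin-2 gene ANGPT2, whose product antagonises TEK, fell from 26.13 ± 0.75 to 1.44 ± 0.94 CPM (adjusted p = 0.000782), and the guidance receptor gene ROBO1 from 52.99 ± 3.08 to 6.55 ± 0.69 CPM (adjusted p = 2.3e-05). Of the Wnt/beta-catenin targets 1 was higher, 5 lower and 3 not called of 9 (1 and 6 adjusted over the list alone; camera adjusted p = 0.105, and 0.0485 without K18). The cyclin gene CCND1 rose by 0.99, and TNFRSF19 and the receptor gene FZD8 fell by 4.39 and 1.49.

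Inflammatory and interferon genes split within each list. Among NF-kappaB targets 9 of 25 were higher, 7 lower and 9 not called (9 and 7 adjusted over the list alone; camera adjusted p = 0.538, direction up, median 0.13, mean -0.13). The leukocyte adhesion gene ICAM1 rose from 24.7 ± 1.96 to 102.2 ± 19.4 CPM (adjusted p = 0.000284) and IL6 from 51.4 ± 5.64 to 119.4 ± 8.54 CPM (adjusted p = 0.000363). The E-selectin gene SELE fell from 1.86 ± 0.25 to 0.313 ± 0.144 CPM and the cyclooxygenase gene PTGS2 from 72.8 ± 1.67 to 10.2 ± 5.0 CPM. For the interferon response 10 of 24 were higher, 5 lower and 9 not called (11 and 5 adjusted over the list alone; camera adjusted p = 0.356, direction up, while fry gave direction down at adjusted p = 0.708). IFIT2 rose by 2.76 and IRF1 by 1.13, whereas BST2, which codes for tetherin, fell by 6.58 and IFI44L by 3.01.

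By camera with its preset correlation, cell cycle genes were lower and antioxidant genes higher as lists. Of 37 cell cycle genes, 8 were lower, 1 higher and 28 not called, but adjusted over the list alone 2 were lower and 0 higher. Over all tested genes 3025 of 14548 were called lower, a share near that of the list. In either direction 38.7% of all tested genes were called, a larger share than in the list. Camera called the list lower at adjusted p = 0.00955, with adjusted p = 0.723 with an estimated correlation, and the call ended without K19 (adjusted p = 0.0961) and by fry (adjusted p = 0.0929). CDK1 fell by 0.86 (adjusted p = 0.0111) and E2F1 by 0.57 (adjusted p = 0.00683), and with the GC-content trend removed the values were -0.56 for CDK1 and -0.98 for E2F1 (adjusted p = 0.0178 and 0.0254). The higher gene was CDT1, at 0.82 (adjusted p = 0.0475), which was not called without WT 1, WT 2, WT 4, K18 or K19 (adjusted p = 0.114, 0.117, 0.156, 0.115 and 0.115), by limma-voom (0.0697), on log2 FPKM (0.0622 to 0.109) or with the GC-content trend removed (0.13, adjusted p = 0.328). MKI67 measured 364.7, 233.9 and 198.5 CPM in K17, K18 and K19 against 367 ± 7.76 in the wild type and was not called (adjusted p = 0.132), but was without K17 (-0.76, adjusted p = 4.94e-05) and by limma-voom with quality weights per group, chosen after seeing the data (adjusted p = 0.033). Of 27 genes for NRF2 and oxidative stress, 15 were higher, 2 lower and 10 not called (17 and 3 adjusted over the list alone), with a camera adjusted p = 0.00701 and adjusted p = 0.211 with an estimated correlation. The aldose reductase gene AKR1B1 rose by 0.48 (adjusted p = 0.00111) and AKR1C3 by 1.34 (adjusted p = 0.00277), a member of a family of near-identical copies whose reads the counting can split. The lower members were the thioredoxin reductase gene TXNRD1 and the cystine transporter gene SLC7A11, which fell by 0.57 and 1.41 (adjusted p = 0.013 and 0.0273). The TXNRD1 call ended without WT 1, WT 4 or K18 (adjusted p = 0.0506, 0.0541 and 0.0502), and that of SLC7A11 without WT 1, WT 2, WT 4, K18 or K19 (adjusted p = 0.0781, 0.0734, 0.0858, 0.0768 and 0.0776) and with no filter on low counts (adjusted p = 0.0659). Among p53, senescence and apoptosis genes 4 of 29 were higher, 3 lower and 22 not called (4 and 3 adjusted over the list alone; camera adjusted p = 0.522). The survival gene BCL2L1 rose by 1.14 and BCL2 fell by 2.47, while the cell cycle inhibitor gene CDKN2A rose by 1.33.

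Several of the genes with the largest changes had 0 counts in 1 group. SIGLEC11, a sialic acid-binding lectin gene, and the epidermal gene CRNN had 0 counts in the wild type and were at least 299-fold and at least 177-fold higher in the knockouts, against a floor of 3 counts over the group. SIGLEC11 shares near-identical exons with SIGLEC16, so its reads can be split between them. SIGLEC16, named after its values were seen, was also near zero in the wild type and rose, from 0.155 to 15.6 CPM. The counts do not show from which of these genes the shared reads came. The lipocalin gene LCN6 had 2 counts in the wild type and 575 in the knockouts, a ratio of 309 with a 95% counting interval of 85.2 to 2560. SCUBE1, a secreted protein gene of endothelium and platelets, rose to 71.3 ± 26.4 CPM, the phosphatase subunit gene PPP2R2C to 83.4 ± 24.1 CPM and the insulin-like growth factor binding protein gene IGFBP5 from 2.08 ± 0.20 to 478.6 ± 294.7 CPM. The other members of the 12 largest increases were the desmosomal gene PKP1, CLIC2, FAM65B (now RIPOR2), SH2D1B, LYPD5 and CPE. In the other direction, the enamel protein gene AMTN, the transcription factor gene SIM1, CRISPLD1 and the potassium channel gene KCNG3 had 0 counts in the knockouts and were at least 278-fold, 235-fold, 166-fold and 153-fold lower. The pseudokinase gene PTK7 fell from 66.2 ± 5.76 to 0.093 ± 0.018 CPM (adjusted p = 3.09e-06). SLITRK4, LYPD1, POSTN, MAL2, FBLN5, GDF6 and AMPH completed the 12 largest decreases, with adjusted p of 0.000101 for GDF6 and below that for the other 6.

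Over all genes, edgeR called 5637 of 14548 tested genes at an adjusted p below 0.05, 2612 higher and 3025 lower in the knockouts. The higher calls outnumbered the lower with a filter of 1 CPM in 3 libraries (2727 and 2442), by DESeq2 (3189 and 3009), without K17 (4776 and 4491) and against a 1.5-fold change (806 and 724). Of the 5637 calls, 1887 changed at least 2-fold, 1033 higher and 854 lower; without K17 the higher ones numbered 1584. More were lower than higher by limma-voom (905 higher, 906 lower) and without K19 (877 higher, 923 lower). Groups did not overlap for 8071 genes (55.5%, against 10% by chance), 5616 of the called genes among them. Component 1 of a principal component analysis held 78% of the variance and separated the groups; component 2 held 13.1% and separated K17 from K18 and K19. Wild-type libraries correlated at Pearson r of 0.997 with each other across genes, knockout clones at 0.974 to 0.985, and libraries of different groups at 0.922 to 0.941. The median SD of log2 CPM over genes was 0.070 in the wild type and 0.186 in the knockouts, a ratio of 2.68, and 1.39 without K17, where 2 clones stand against 3 wild-type libraries. The count of called genes was 3081, 3360 and 3020 without WT 1, WT 2 and WT 4, and 9267 without K17.

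**Figure D3:**
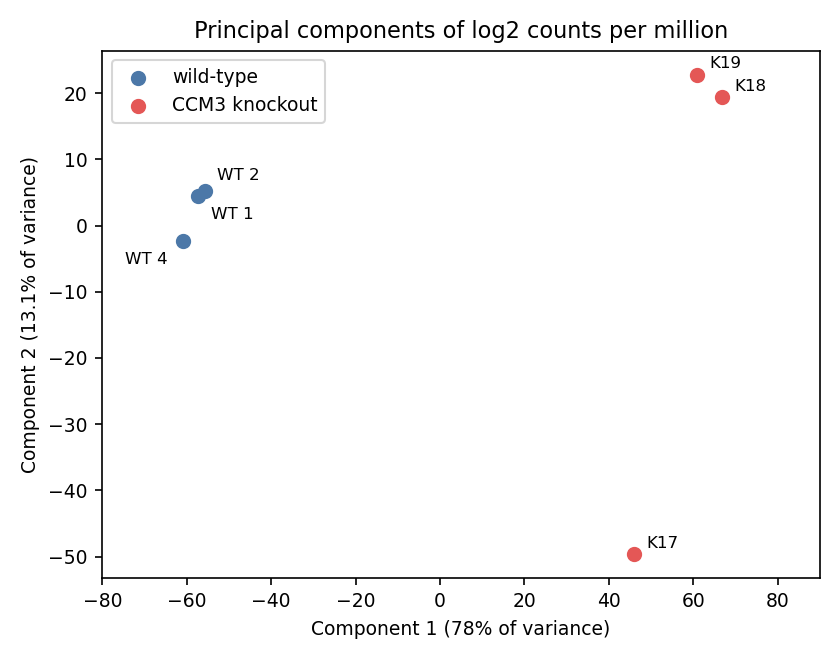
First and second principal components of log2 CPM; blue points are wild-type libraries and red points knockout clones. Component 1 (78% of the variance) separated the groups and component 2 (13.1%) set K17 at -49.6 apart from K18 at 19.5 and K19 at 22.8.

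The libraries K18 and K19 stood apart by transcript GC content. For the 2106 tested genes with a GC content of 60% or more, the median log2 ratio to the wild-type mean was 0.76 in K18 and 0.73 in K19 but -0.06 in K17. For the 1301 genes under 40% it was -0.35 in K18, -0.28 in K19 and -0.17 in K17. Called genes higher in the knockouts had a median GC content of 55.3%, and those lower 44.5%. With the trend of each library on GC content removed, a setting chosen after seeing the data, 4214 of the 5282 called genes with a GC value kept their call and direction, and 0 were called in the opposite direction. Of the 1722 with at least a 2-fold change, 1669 kept call and direction, 1411 of them with at least a 2-fold change still. Among the 13248 genes with a GC value, calls with at least a 2-fold change were 937 higher and 785 lower before the removal, and 721 higher and 840 lower after it.

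**Figure D4:**
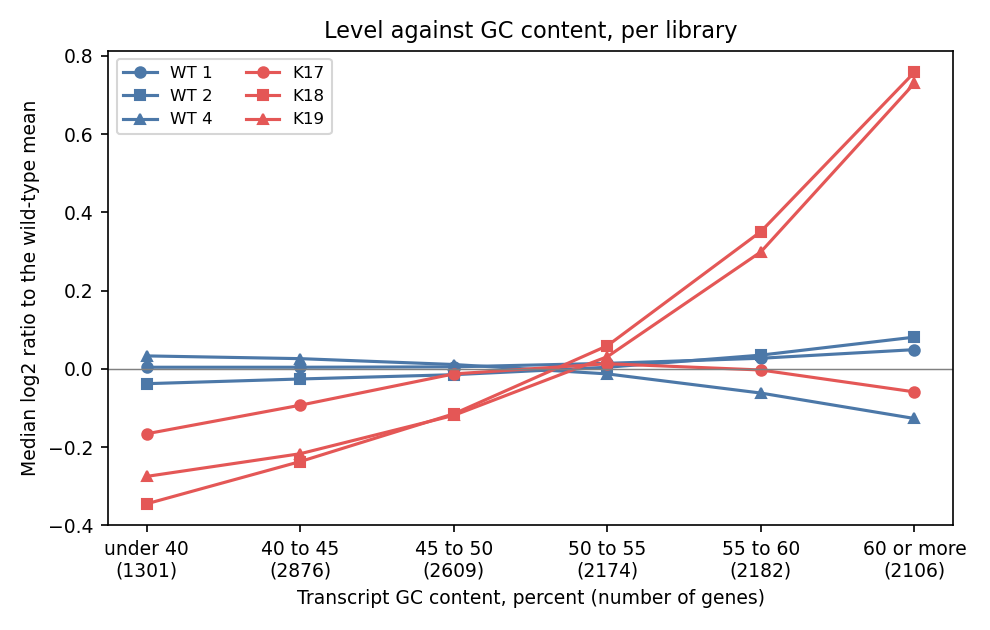
Median log2 ratio to the wild-type mean, by class of transcript GC content (percent, number of genes in brackets), for each library; blue lines are wild-type libraries and red lines knockout clones. K18 and K19 rose from -0.35 and -0.28 in the class under 40% to 0.76 and 0.73 in the class of 60% or more, while K17 stayed between -0.17 and 0.01.

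The authors' deposited table of their own comparison held 20833 genes and 5886 calls at an adjusted p below 0.05, 3004 higher and 2882 lower in the knockouts. Over the 14539 genes in both tables, edgeR called 5633 genes, and 5730 were called in the authors' deposited table. Both called 5201 genes, 92.3% of the edgeR calls, and all 5201 had the same sign. For PDCD10 the authors' deposited table gave a log2 fold change of -0.69 with a standard error of 0.14, and for FN1 -2.36 with a standard error of 0.11.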

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

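Quality weights per group, thinning to the same total and removal of the GC-content trend were chosen after seeing the data. PDCD10 stayed lower and called in all 20 alternatives, between -0.81 and -0.51 on the log2 scale, with adjusted p from 2.94e-06 to 0.0227. For the 140 other tested named genes, 2717 of 2767 alternative values kept direction and side of the threshold, 43 lost the call, 7 gained it and 0 reversed. On log2 FPKM, limma gave 735 genes with at least a 2-fold change (440 higher, 295 lower) with a pseudocount of 1, 1012 (576 and 436) with 0.1, and 718 (429 and 289) with no filter (test, scaling and genes tested differ too, and the cause was not tested). The share of calls that were higher was 46.3%, and between 37.4% (log2 FPKM, no filter) and 52.8% (a filter of 1 CPM) in the alternatives. Against a 1.5-fold change 1530 genes were called (806 higher, 724 lower), and at an adjusted p below 0.01 2887 (1312 and 1575), as fewer genes pass a stricter test. With each library left out, calls ranged from 3020 to 9267, those higher from 1370 to 4776, those lower from 1650 to 4491, changes of at least 2-fold from 1467 to 2611, higher ones among them from 751 to 1584 and lower ones from 713 to 1027. The most calls came without K17, although fewer samples enter each such fit. The median SD of the knockouts was 0.186 with K17 and 0.097 without it, from K18 and K19 alone. Its part in the rise of calls was not tested. The ratio of median SDs ranged from 1.392 to 3.967 without each library. All 6 list calls were lost with an estimated correlation (0 lists called). Fry called 19, 5 of the 6 among them. Higher by fry beyond these were the lists for the CCM complex, integrins, NF-kappaB, hypoxia, coagulation, autophagy and fibroblast markers. Lower were those for arterial and venous, lymphatic, fibronectin and collagen, Wnt, angiogenic, unfolded protein response, and smooth muscle and pericyte genes. Genes called in both analyses numbered 2853 at an adjusted p below 0.01 and 1698 with at least a 2-fold change, and DESeq2 shared 5881 of the authors' 5882 calls. Removal of the GC-content trend left 5682 calls over 13248 genes and 8 lists. In simulation edgeR recovered 34.3% of 1.5-fold changes and DESeq2 62.7%, but edgeR called 0.08% of unchanged genes and DESeq2 0.42%. Depth limits the ratio of a gene with 0 counts in a group to a lower bound.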

Other observations

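Tests of fibroblast and smooth muscle markers and of chromosomes among the near-zero genes, thinning, the GC-content trend and the bootstrap interval of Spearman's rho were chosen after the result was seen. The lists for hypoxia, the unfolded protein response, cholesterol synthesis and autophagy were not called by camera. Fry called hypoxia and autophagy higher (adjusted p = 0.00548 and 0.00791) and the unfolded protein response lower (adjusted p = 0.0402). It did not call cholesterol synthesis (adjusted p = 0.322). Single members were called, as were 38.7% of all tested genes. Of 29 hypoxia and glycolysis genes, 7 were higher, 10 lower and 12 not called (10 and 11 adjusted over the list alone; camera adjusted p = 0.85, direction up, with a median of -0.02 and a mean of 0.07). NDRG1 rose from 33.8 ± 0.33 to 236.6 ± 17.1 CPM (adjusted p = 8.43e-06 by edgeR) and the glucose transporter gene SLC2A3 rose by 0.57, while the glycolytic regulator gene PFKFB3 fell by 0.72 and the collagen prolyl hydroxylase gene P4HA1 by 0.60. For the unfolded protein response 3 of 23 were higher, 8 lower and 12 not called (3 and 8 adjusted over the list alone; camera adjusted p = 0.254). The chaperone gene HYOU1 fell by 0.63 and the asparagine synthetase gene ASNS by 1.19, while PPP1R15A rose by 0.52 (0.29 with the GC-content trend removed, adjusted p = 0.04). Cholesterol synthesis held 3 higher, 1 lower and 16 not called of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.522), with STARD4 higher by 0.47 and SC5D having fallen by 0.56 (-0.31 with the trend removed, adjusted p = 0.00253). Autophagy and lysosome genes held 11 higher, 3 lower and 15 not called of 29 (11 and 3 adjusted over the list alone; camera adjusted p = 0.161). The lysosomal cholesterol transporter gene NPC1 rose by 0.83 and the transcription factor gene TFE3 by 0.76, while WIPI1 and LAMP2 fell by 0.82 and 0.55. With the GC-content trend removed TFE3 was at 0.43 and LAMP2 at -0.34 (adjusted p = 0.0106 and 0.00676).

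Genes near zero in all 3 knockout clones numbered 56, defined as at least 2 CPM in every wild-type library and at most 10 counts in each clone, against 21 near zero in the wild type; MST4, POSTN, FBLN5, PTK7 and, named after its values were seen, the sulfotransferase gene SULT1E1 (115.3 ± 2.17 CPM in the wild type) were among the 56. Fibroblasts or smooth muscle cells in the wild-type cultures would bring all their abundant transcripts. The 12 tested markers of the fixed lists had a median log2 fold change of 0.33 (bootstrap interval -1.07 to 1.47, with 4 higher and 3 lower). COL1A1 stood at 0.220 CPM in the wild type against 137.2 for POSTN. The median pools both lists and holds PI16 and S100A4, which rose from low wild-type levels, and MCAM, which endothelium shares. It therefore cannot decide on pericyte-like cells. RGS5, TAGLN and NOTCH3 fell, and fry called the smooth muscle and pericyte list lower (adjusted p = 0.00364, against 0.602 by camera), so such cells stay open. Loss of whole chromosomes was argued against by 0% of the set lying on a chromosome with a median log2 ratio of at most -0.4 in all clones, and loss of segments by 3.6% having a near-zero neighbour. More of the set was X-linked than in the background (8 of 55, 14.5% against 3.4%, odds ratio 4.95, 95% interval 2.01 to 10.7, two-sided Fisher's exact p = 0.000476, adjusted p = 0.0109 over 23 chromosomes), and chromosome 4 was over-represented too (odds ratio 3.92, adjusted p = 0.0407). MST4 was among the X-linked genes. An effect of CCM3 loss and a difference between clones and the wild-type lines stay open, as the design confounds them.

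The knockout clones varied more than the wild-type libraries, with a ratio of median SDs of 2.68 and a biological coefficient of variation of 24.5% against 3.87%. The ratio stayed at 2.619 after thinning to the same depth, 2.733 with the GC-content trend removed, and 2.877 (2.853 before) after centring each clone on its chromosome medians, which argues against depth, GC content and whole-chromosome copy number as the whole cause. Without K17 it was 1.392, but an SD of 2 clones is lower than that of 3 by construction. By pairs, the median SD was 0.179 for K17 with K18, 0.181 for K17 with K19 and 0.097 for K18 with K19, against 0.065, 0.059 and 0.047 for pairs of wild-type libraries, which argues against K17 as the whole cause. Biological differences between the clones were not tested and stay open, as does the source of the GC trend of K18 and K19.

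A candidate explanation for matrix genes going both ways was that the most abundant ones fell. Across the 39 tested matrix genes, which are not independent replicates, Spearman's rho between wild-type level and log2 fold change was -0.157 (permutation p = 0.341, 100000 permutations; Pearson's r = -0.089). The bound set beforehand against the explanation, a permutation p of 0.05 or more, was met, but it was wrong as a bound, since the bootstrap interval of rho over genes (-0.425 to 0.124) holds both negative values and 0, so the relation stays undecided.

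For the count of called genes, the 10 splits of the 6 samples into groups of 3 are too few for a share under 0.05. The real split gave 5637 calls and the highest of the others 0, so that 1 of the 10 splits gave as many. Each of the other splits mixed wild-type and knockout libraries on a side, so the group difference widened the spread within sides. The 0 is therefore no null level for the 5637 calls.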
